A study of Mus musculus with 2 samples.

How the data were processed

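H3K4me3 ChIP-seq of neural tube from mouse embryos at embryonic day 13.5 was available as 4 deposited peak lists from 2 biological replicates, which formed 1 group. The replicate numbers and the group were taken from the labels. Libraries were size-selected, and a control experiment is named, per the labels. The text deposited with the lists states that the peaks of each replicate were derived from its filtered alignments and control reads, that the pooled list was made from both replicates and that the replicated list was derived from the pooled list and the lists of both replicates. Coordinates are in mm10, per the labels. The aligner, the peak caller, their versions and their settings are not given in the sources used here.

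Each deposited list is in narrowPeak format and gives, for each peak, a signal value, the −log10 of a p-value, the −log10 of a q-value and the position of the summit. The signal values were set by the authors' caller and deposited per peak. They were used only to rank or describe peaks within a list. The lowest deposited −log10 p was 2.15 in replicate 1, 2.04 in replicate 2, 2.00 in the pooled list and 2.43 in the replicated list, so weak peaks are part of the lists. Peaks with a q over 0.01 made up 6.31%, 9.80%, 5.12% and 0.175% of these lists in the same order. The lists hold no read counts, so the depth of each library is unknown and no interval that needs it is given. A gene without a peak is one below the authors' threshold, not one shown to lack the mark.

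Start sites came from the GENCODE mouse release 21 annotation of GRCm38, the assembly that mm10 names, and no peak extended past the end of a chromosome in the GRCm38 sequence. All transcripts were used, which gave 132721 distinct start sites for 55413 genes and 93513 for 21938 protein-coding genes. A gene was called marked when a peak lay within 1 kb of any of its start sites, so that a peak near several genes marked each of them, and 2788 of the 14612 marked genes (19.1%) had only peaks of this kind. Domains were made by joining peaks of a list across gaps of up to 1 kb, and the breadth of a gene is the length of its widest domain. The CpG observed/expected ratio was computed in the 500 bp on each side of a start site, and the highest value of the gene was kept. Distal peaks lay over 10 kb from any start site. Peaks on unplaced or unlocalized scaffolds were left out of the gene analyses because the start sites used were on the 21 assembled chromosomes.

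The 22 gene lists, the tests and the rule for named genes were fixed before the data were examined. A total of 393 symbols in 21 lists were written by hand and 393 were found in the annotation, and the sensory receptor list was a name pattern that took 1420 genes. The text names, for each list, up to 4 marked members with the highest signal value at a start site and up to 4 unmarked members in list order. It also names the 15 protein-coding genes with the broadest domains (1 per domain, the gene whose start site is nearest the strongest peak), the 5 strongest distal peaks and up to 5 genes marked in the list of 1 replicate alone. Other names are said to have been chosen after their values were seen, or carry a shared peak.

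Replicates were compared by the share of peaks that overlap by at least 1 bp, by correlation of the signal value across one-to-one pairs of largest overlap, and against 100 circular shifts of the peaks along each chromosome. Marking of each list was tested with a two-sided Fisher's exact test against the other protein-coding genes. Breadth was tested with a two-sided permutation test on the median of 100000 random lists of the same size drawn from marked genes, for lists with at least 5 marked members. Both were adjusted by the Benjamini-Hochberg method over the lists, with a threshold of 0.05. Genes and peaks are not independent replicates, so these p-values describe the lists in this tissue. With 1 group there was no test between conditions.

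The procedures were tested on simulated data. In 21938 genes, the marking test called 84% of simulated lists of 20 genes that were marked at 97%, and 0% of unchanged lists. In 14612 marked genes, the breadth test called 100% of lists of 20 with breadth doubled and 2% of unchanged lists. Simulated marks and breadths did not depend on CpG content or shared peaks, so these rates do not cover such effects in the real lists. A simulated replicate that kept 80.2% of 29144 peaks was found to share 80.7%.

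The alternatives set beforehand were other overlap rules, a q of 0.01 or lower, the 20000 strongest peaks by p of each list, −log10 p in place of the signal value, windows of 0.5 kb and 2.5 kb, no joining and joining across 3 kb, the pooled list, each replicate's list alone, and random lists matched on CpG observed/expected in 10 bins. Chosen after the data were seen were the count of lists past the threshold, start sites of GENCODE basic transcripts, leaving out genes that share every peak with another gene, counting each domain once, and random lists matched on signal value. A result that did not pass and then passed in the other direction was counted as reversed, a rule also set after the data were seen. A set of 13 terminal marker genes was narrowed to the 6 that are not globins after its result was known, and both are reported. The tests of Hox groups, of spinal against forebrain factors and of CpG-rich germline genes were left out once their results were known and then put back. The rules for judging the tests of CpG content and signal value were reworded after their values were known, and the random shift of simulated peaks was lowered after larger shifts touched neighbouring peaks. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1.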

Results

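Histone H3 trimethylated at lysine 4 (H3K4me3), a chromatin mark found at active and poised promoters, was mapped by ChIP-seq in mouse neural tube, the embryonic precursor of the spinal cord and brain. The tissue came from healthy B6NCrl embryos at embryonic day 13.5, with males and females pooled. There was 1 group of 2 biological replicates and no second tissue, age or treatment, so no comparison between conditions was possible. The 2 replicates gave 29157 and 29961 peaks (mean 29559 ± 569, SD, n = 2), which covered 40.98 ± 0.559 Mb. The authors' list called on both replicates together held 30902 peaks, and their replicated list held 24521. The lists carry no read totals, so the sequencing depth is unknown. Signal values are the authors' own and are used here only to rank peaks within a list.

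The first question was which promoters carried the mark in this tissue. Genes of the progenitor, patterning and pan-neuronal lists did so without exception, and so did cell cycle and housekeeping genes. For comparison, 66.6% of all protein-coding genes were marked. Of genes with a CpG observed/expected ratio of 0.6 or more, 98.8% were marked. A replicated peak lay within 1 kb of a start site at 20 of 20 neural progenitor genes, 15 of 15 dorsal patterning genes, 12 of 12 ventral patterning genes and 23 of 23 pan-neuronal genes. Among the progenitor genes the strongest signal values were those of Msi1 (70.7), which encodes an RNA-binding protein of stem cells, the Notch ligand Dll1 (63.7), the Notch effector Hes5 (61.1) and the intermediate filament gene Vim (55.8). The peak of Hes5 also lay within 1 kb of Pank4. In the pan-neuronal list Elavl3 (71.6), Ncam1 (69.3), Tubb3 (63.9) and Ina (62.7) led, and the peak of Ina also lay at Nt5c2. Of the spinal neuron transcription factors 25 of 26 were marked, led by the dorsal interneuron factor Lbx1 (48.5), Pou4f1 (41.3), Lhx5 (40.8) and Lhx1 (37.9), while Phox2b, a factor of visceral motor neurons, had no peak within 1 kb but had one within the 2.5 kb window. The shares of the neural lists named here were identical in the lists of both replicates (SD 0, n = 2).

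Peaks at the patterning genes ranked low in strength. Dorsal genes were led by Bmp4, a roof plate signal (37.4), Msx2 (29.2), Pax3 (23.7) and Gdf7 (21.1). Ventral genes were led by Irx3 (34.2), Shh, the floor plate signal (31.2), Nkx6-1 (22.6) and Prdm12 (17.9). The median signal value of marked genes was 16.9 in the dorsal and 10.97 in the ventral list, at the median percentiles 10.4 and 6.60 of all marked genes. Other lists ranked about as low, with medians of 16.1 for spinal neuron, 11.4 for forebrain and midbrain, 12.4 for endothelial and 18.1 for mesenchyme genes. The median was 45.0 for progenitor genes and 60.4 for housekeeping genes such as Ubc (76.2), Eef1a1 (75.7), Ywhaz (75.0) and Gapdh (71.5). The peak of Ubc also lay at Gm10382.

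Genes of later neural function were also marked. All 22 synaptic maturation genes had a peak, with the highest signal values at the potassium channel gene Kcnc1 (61.7), Homer1 (60.8), Gabra2 (59.8) and Syn2 (57.6). The glial list was divided: 12 of 19 members were marked, led by the glutamate transporter gene Slc1a2 (55.3), Mbp (46.5), Cnp (40.3) and Slc1a3 (32.4), whereas the astrocyte genes Gfap, Aqp4 and S100b and the myelin gene Mog had no peak. Of the forebrain and midbrain transcription factors 19 of 21 were marked, led by Dlx2 (24.7), En2 (19.3), Dlx5 (17.8) and Dlx1 (15.4), and Otx2 and Fezf2 were unmarked in the replicated list. The share was 95.2 ± 6.73% in the replicates' own lists (SD, n = 2). Otx2 had a weak peak in replicate 1 alone (signal value 2.90), and Fezf2 had weak peaks in both replicates (2.77 and 2.66) that the replicated list did not hold.

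Lists written for other lineages, neural crest included, were unevenly marked. The endothelial list had 14 of 15 members marked, led by the VEGF receptor gene Kdr (51.0), Egfl7 (30.5), Erg (24.96) and Cldn5 (23.3), with Tie1 unmarked (96.7 ± 4.71% in the replicates, SD, n = 2). The peaks of Egfl7 also lay at Gm20532. The mesenchyme and cartilage list had 16 of 18 marked, led by Runx2 (41.2), Tcf15 (32.6), Meox2 (26.2) and Acan (24.8), with Meox1 and Lum unmarked. The neural crest and peripheral nervous system list had 13 of 15 marked, with Avil and Dbh unmarked. Its highest values were at Mpz (68.8), whose peaks lie partly at Sdhc, and at Pou4f1 (41.3), Isl1 (31.5) and Runx1 (30.3), of which Pou4f1 and Isl1 are also in the spinal neuron list. The epithelial list had 9 of 14 marked, led by Krt10 (34.3), Krt1 (30.3), Epcam (29.6) and Cdh1 (23.4), with Krt5, Krt14, Krt15 and Trp63 unmarked (60.7 ± 5.05% in the replicates, SD, n = 2).

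Muscle, heart, blood, liver and germline genes were mostly unmarked. In skeletal muscle 4 of 15 genes had a peak, among them Ckm (26.2), whose peak also lay at Klc3, and Myod1 (8.09), while Myf5, Myog, Actc1 and Acta1 had none. In the cardiac list 4 of 13 had a peak, led by the calcium release channel gene Ryr2 (55.6) and Actn2 (23.3), and Nkx2-5, Tbx5, Myh6 and Myh7 had none. In the replicates' own lists the shares were 23.3 ± 4.71% for skeletal muscle and 34.6 ± 5.44% for cardiac genes (SD, n = 2). The erythroid list had 5 of 18 marked, led by Gypa (28.7), Klf1 (25.8), Nfe2 (14.05) and Epor (12.2), and none of its 7 globin genes, Hbb-bs, Hbb-bt, Hbb-y and Hbb-bh1 included. Hbb-bs and Hbb-bt are near-identical copies, and how reads shared between copies were treated is not given in the sources used here. The microglia and macrophage list had 1 of 15 marked, Hexb (33.03), and Csf1r, Spi1, Ptprc and Aif1 had no replicated peak (16.7 ± 4.71% in the replicates, SD, n = 2, and 4 of 15 in the pooled list). The liver list had 1 of 17, Foxa3 (64.8), whose peak also lay at Sympk, and Alb, Afp, Apoa1 and Apoa2 had none, while 3 of 17 were marked with a 2.5 kb window and 0 of 16 without Foxa3, whose only peak is shared. Of the pluripotency and germline genes 3 of 16 were marked, Klf4 (39.8), Esrrb (23.9) and Dazl (21.4), and Pou5f1, Nanog, Zfp42 and Dppa3 were unmarked (21.9 ± 4.42% in the replicates, SD, n = 2, and 5 of 16 in the pooled list).

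Ubiquitous genes and sensory receptors stood at the ends of the range. All 20 cell cycle genes were marked, led by Aurka (68.9), Mcm6 (62.7), Mki67 (58.1) and E2f1 (54.3), with the peak of Aurka shared with Cstf1, as were all 20 housekeeping genes. Of 1420 olfactory and vomeronasal receptor genes 4 were marked (0.282%): Vmn1r4 (49.9), whose peak also lay at Nt5c3, Olfr94 (43.0), Olfr658 (8.90) and Olfr1033 (7.52).

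**Figure D1:**
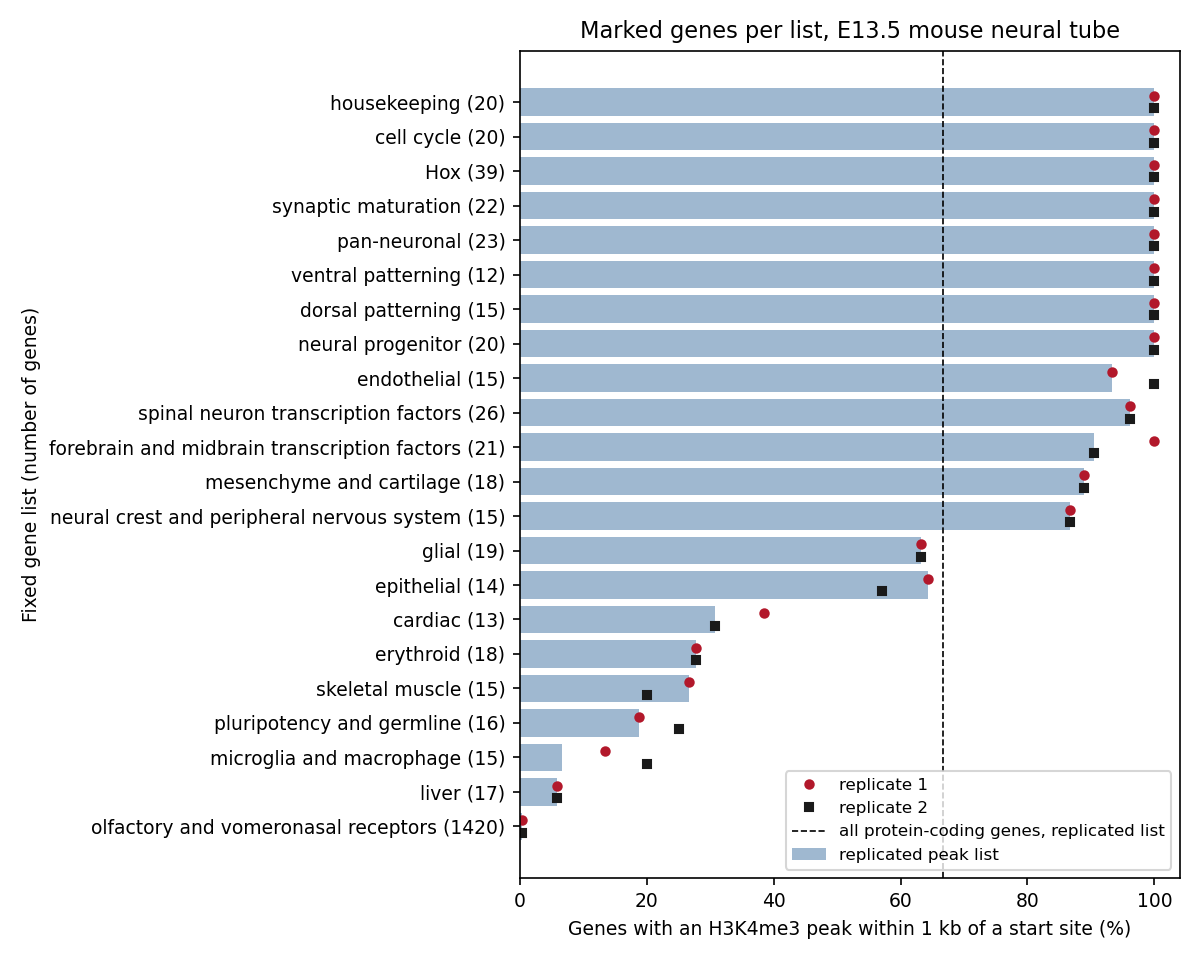
Share of the genes of each fixed list (vertical axis, number of genes in brackets) with an H3K4me3 peak within 1 kb of a start site (horizontal axis, %), with bars for the replicated list, circles for replicate 1, squares for replicate 2 and a dashed line for all protein-coding genes (66.6%). All progenitor, pan-neuronal and Hox genes were marked, and liver (5.88%) and sensory receptor genes (0.282%) lay lowest.

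Among all 21938 protein-coding genes 14612 (66.6%) were marked in the replicated list, and 66.7 ± 0.0677% (SD, n = 2) in the lists of the replicates. After the peaks were shifted along the chromosomes, 6.55% were marked on average over 100 shifts. Two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 22 lists, placed 11 lists above and 7 below the other genes. In Fisher's exact test the lists above included Hox (adjusted p = 1.77e-06), pan-neuronal and synaptic maturation (0.000534 each), neural progenitor (0.00102), spinal neuron (0.00112), dorsal (0.00641), ventral (0.0169), forebrain and midbrain (0.0253) and endothelial genes (0.0339). Cell cycle and housekeeping genes (0.00102 each) were the others. The lists below were liver (2.02e-06), microglia and macrophage (1.21e-05), pluripotency and germline (0.000518), erythroid (0.0028), skeletal muscle (0.0031), cardiac (0.0192) and sensory receptor genes, whose p was too small for the computation to hold. Mesenchyme (0.0542), neural crest (0.184), glial (0.847) and epithelial genes (adjusted p = 1) did not pass the exact test. Genes, not animals, are the units of these tests, which describe this tissue and no difference between conditions.

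Marking differed with start-site sequence. Of the 11528 genes with a CpG observed/expected ratio of 0.6 or more, 98.8% were marked, against 11.3% of the 7471 genes under 0.4. Against 10000 random lists matched on that ratio, 3 of the 22 lists had an adjusted p under 0.05. Endothelial genes were marked more often than matched genes (93.3% against 56.4%, adjusted permutation p = 0.00293). Pluripotency and germline genes (18.8% against 69.6%) and sensory receptor genes (0.282% against 6.33%) were marked less often (adjusted permutation p = 0.0022 each, the smallest possible here). For 8 lists called higher in the exact test, progenitor, dorsal, ventral, spinal neuron, forebrain and midbrain, Hox, cell cycle and housekeeping, matched genes were marked so often (92.9 to 98.5%) that no count could have passed the matched test as higher, even before adjustment. Pan-neuronal and synaptic maturation genes were all marked and had adjusted permutation p of 0.0968 and 0.13. No higher count was possible for them, so they could not have passed after adjustment either. Liver (5.88% against 22.7%, adjusted permutation p = 0.159) and microglia and macrophage genes (6.67% against 23.4%, 0.173) lay below matched genes without passing. The direction changed for 2 lists: erythroid genes lay above matched genes (27.8% against 22.5%, 0.918). Forebrain and midbrain factors lay below them (90.5% against 96.7%, 0.398). The endothelial call of the exact test was not made with a 2.5 kb window (adjusted p = 0.0628), and the cardiac call was not made with that window (0.156) or with the pooled list (0.16).

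The second question was how broad the mark was at each gene. Genes of 6 neural lists (progenitor, dorsal, ventral, spinal neuron, pan-neuronal and Hox) carried domains broader than those of other marked genes, where a domain is a run of replicated peaks joined across gaps of up to 1 kb. The median was 2464 bp over all marked genes, 6887 bp for the 25 spinal neuron transcription factors, 6465.5 bp for the 20 progenitor genes and 5402 bp for the 23 pan-neuronal genes. Medians in the replicates' own lists were 6675 ± 170 bp, 6472.5 ± 5.66 bp and 5543.5 ± 202 bp (SD, n = 2). Lhx1 lay in a domain of 22104 bp, Lhx5 of 17268 bp and Lbx1 of 10739 bp. Msi1 had 9735 bp, Dll1 6431 bp and Tubb3 7927 bp. All 23 pan-neuronal genes and 24 of the 25 spinal factors were above the median of the other marked genes.

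The neural crest and peripheral nervous system list had a median of 6380 bp, with 10981 bp at Isl1 and 6380 bp at Runx1. Dorsal patterning genes had 3735 bp, with 11213 bp at Pax3 and 1687 bp at Gdf7, and ventral genes 3565 bp, with 9918 bp at Prdm12 and 4771 bp at Shh. Housekeeping genes had 3457.5 bp, with 6054 bp at Ywhaz. Forebrain and midbrain transcription factors were narrower than other marked genes, at 1546 bp, with 2791 bp at Dlx2 and 2141 bp at En2. Cell cycle genes had 2667.5 bp, glial genes 2570.5 bp, endothelial genes 2365.5 bp, epithelial genes 1658 bp and erythroid genes 1404 bp.

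In a two-sided permutation test of each list's median against 100000 random lists of marked genes, 8 lists were broader and 1 narrower among the 16 lists with at least 5 marked members. Progenitor, spinal neuron, pan-neuronal, Hox and neural crest genes each had an adjusted p of 6.4e-05, the smallest that these permutations allow here. Dorsal (adjusted p = 0.0181), ventral (0.0481) and housekeeping genes (0.0189) were broader and forebrain and midbrain factors narrower (0.00256) in the same permutation test. Synaptic maturation genes (3074 bp, adjusted p = 0.0952) and mesenchyme genes (3307 bp, 0.063) did not pass the permutation test. Their outcome varied with the setting: both passed as broader against CpG-matched lists (adjusted permutation p = 0.0224 and 0.0227). Neither passed with 3 kb joining (0.235 and 0.0594). With peaks left unjoined the medians of spinal neuron (3311 bp, adjusted permutation p = 0.0053) and neural crest genes (4157 bp, 0.00048) were lower and dorsal (2437 bp, 0.852) and ventral genes (2605.5 bp, 0.617) were not called, while 3 kb joining gave spinal neuron genes 11234 bp and ventral genes 6264.5 bp and ended the calls of forebrain (2141 bp, 0.257) and housekeeping genes (3526.5 bp, 0.0512). Against lists matched on signal value housekeeping genes were not called (adjusted permutation p = 0.0813), and the median of forebrain and midbrain factors was above the 1056 bp of the matched lists (0.0759).

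**Figure D2:**
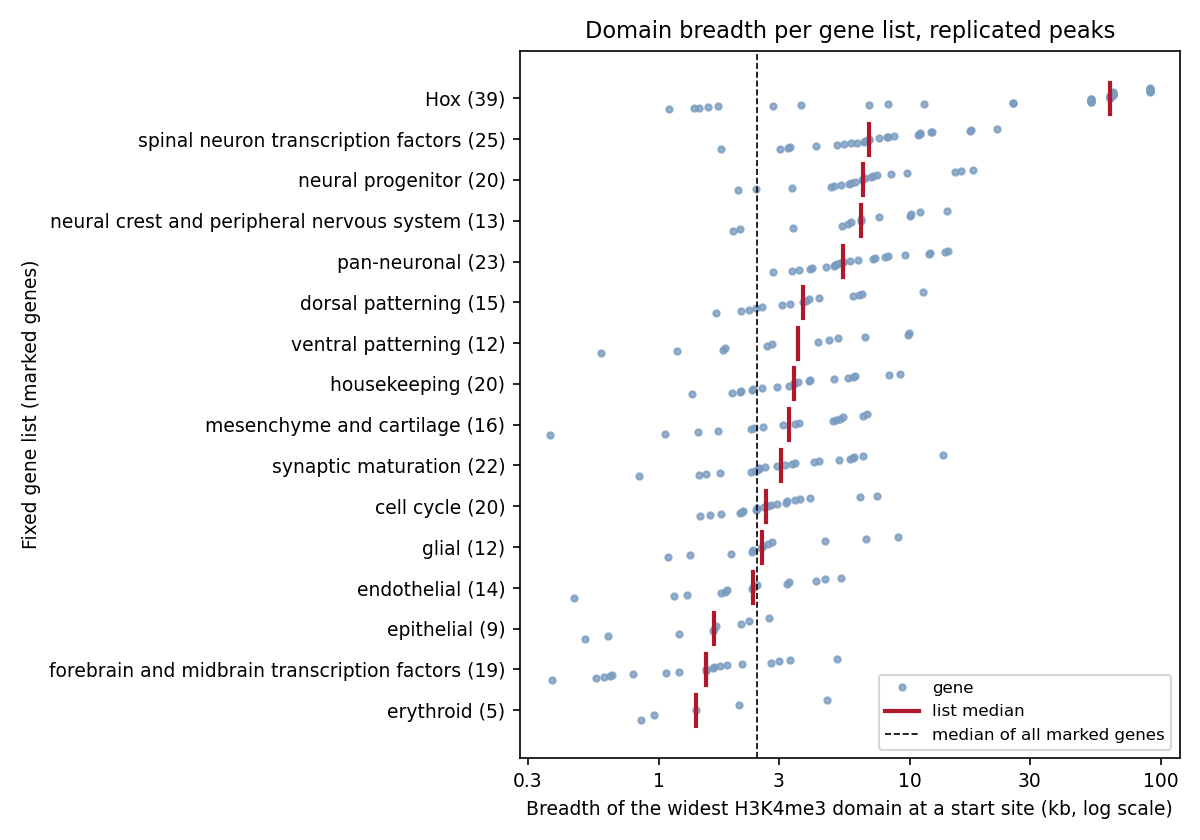
Breadth of the widest H3K4me3 domain at a start site (horizontal axis, kb, log scale) for each marked gene (points) of the 16 lists tested (vertical axis, marked genes in brackets), in the replicated list, with red bars for list medians and a dashed line for the median of all marked genes (2464 bp). Spinal neuron factors (median 6887 bp) lie mostly to its right, and forebrain and midbrain factors (1546 bp) mostly to its left.

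Among domains with a protein-coding start site, the broadest lay on the Hox clusters, whose genes set position along the body axis. Naming each such domain by the protein-coding start site nearest its strongest peak, the 5 broadest were those of Hoxb6 (90.1 kb, chromosome 11, 96266124 to 96356177), Hoxc9 (64.3 kb, chromosome 15, 102953214 to 103017470), Hoxd4 (62.4 kb, chromosome 2, 74678725 to 74741167), Hoxa3 (52.6 kb, chromosome 6, 52188904 to 52241494) and Hoxa1 (25.7 kb, chromosome 6, 52155734 to 52181421). The widest domain at the same place in the replicates' own lists was 89.8 ± 0.191 kb for Hoxb6, 50.5 ± 10.3 kb for Hoxc9, 47.4 ± 22.7 kb for Hoxd4, 49.2 ± 4.94 kb for Hoxa3 and 25.3 ± 0.499 kb for Hoxa1 (SD, n = 2). The Hoxd4 domain measured 31359 bp in replicate 1 and 63474 bp in replicate 2.

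Outside the Hox clusters, the broadest domains with a protein-coding start site began with that of Nr2f2. A domain without one, at Mir9-2 and named after its value was seen, was broader than it (29.8 kb). Nr2f2, which encodes a nuclear receptor, had 25.2 kb (25.3 ± 0.173 kb in the replicates, SD, n = 2), Meis2, a Hox cofactor, 24.5 kb (22.8 ± 2.09 kb), and Ebf3 23.7 kb (24.7 ± 3.32 kb). Next came the domain of 22.1 kb (22.1 ± 0.608 kb) named Aatf by the rule, which also holds the start of Lhx1. Pou3f3 had 21.9 kb (21.3 ± 0.713 kb), the Hedgehog receptor gene Ptch1 20.8 kb (20.4 ± 2.71 kb) and Nfib 20.1 kb (20.1 ± 0.0849 kb). Tshz1 had 18.4 kb, Sox2, a core factor of neural progenitors, 17.8 kb, and Lmx1b 17.5 kb (18.1 ± 0.433 kb). The domains of Tshz1 (14.1 ± 0.0856 kb) and Sox2 (10.6 ± 0.0792 kb) were shorter in the replicates' own lists than in the replicated list, which takes its peaks from the pooled call.

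Within the clusters, all 39 Hox genes were marked in the replicated list and in both replicates. Peaks covered 81.8% of Hoxa (78.4 ± 3.28% in the replicates, SD, n = 2), 81.2% of Hoxc (73.5 ± 7.91%), 73.9% of Hoxd (70.4 ± 1.25%) and 56.7% of Hoxb (55.5 ± 0.561%). Cluster lengths from the first to the last Hox gene body were 105.3 kb, 115.8 kb, 96.8 kb and 173.9 kb in that order. The median breadth over Hox genes was 62443 bp, but they share domains: with each domain counted once, 15 domains had a median of 6845 bp, still above the 2384 bp of random lists (permutation test, adjusted p = 6.4e-05). The median over Hox genes was 10909 bp with peaks left unjoined, and with joining 31359 bp in replicate 1 and 52648 bp in replicate 2.

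Signal values were lower in the posterior paralogue groups. Low values also occurred among the anterior groups: group 1 had a median of 42.5. Hoxb1 (13.6) and Hoxc4 (24.6), named after their values were seen, were weak as well. Hoxd3 and Hoxd4 (72.9 each, with a shared peak) and Hoxb3 and Hoxb4 (72.1 each, with a peak shared up to Hoxb9) were the strongest. The median was 69.3 over the 27 genes of paralogue groups 1 to 9 and 12.6 over the 12 genes of groups 10 to 13 (two-sided permutation test chosen after the values were seen, p = 2e-05, the smallest it can give). Genes that share a peak share its value, so these genes are not independent. The medians were 69.3 and 14.7 in Hoxa, 55.1 and 11.7 in Hoxc, and 59.2 and 15.1 in Hoxd, and in Hoxb the median of groups 1 to 9 was 72.1 and Hoxb13 was the only gene of the later groups. Group 10 stood above groups 11 to 13, with a median of 42.6 over Hoxc10 (64.5), Hoxd10 (42.6) and Hoxa10 (40.9), against group medians of 14.7, 6.67 and 7.90. Hoxc10 had the same value as Hoxc9, and Hoxd10 the same as Hoxd9, so the step at group 10 is not independent of group 9. In replicate 1 the values were 29.0 for Hoxc10 against 49.7 for Hoxc9, and 23.5 for Hoxd10 against 37.5 for Hoxd9. In replicate 2 Hoxc10 and Hoxc9 had the same value (55.3), as did Hoxd10 and Hoxd9 (35.8). The 4 genes of group 13, named after their values were seen, were Hoxa13 (7.78), Hoxb13 (6.90), Hoxc13 (8.03) and Hoxd13 (10.9), and Hoxd12 (4.26) was the weakest of the 39.

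**Figure D3:**
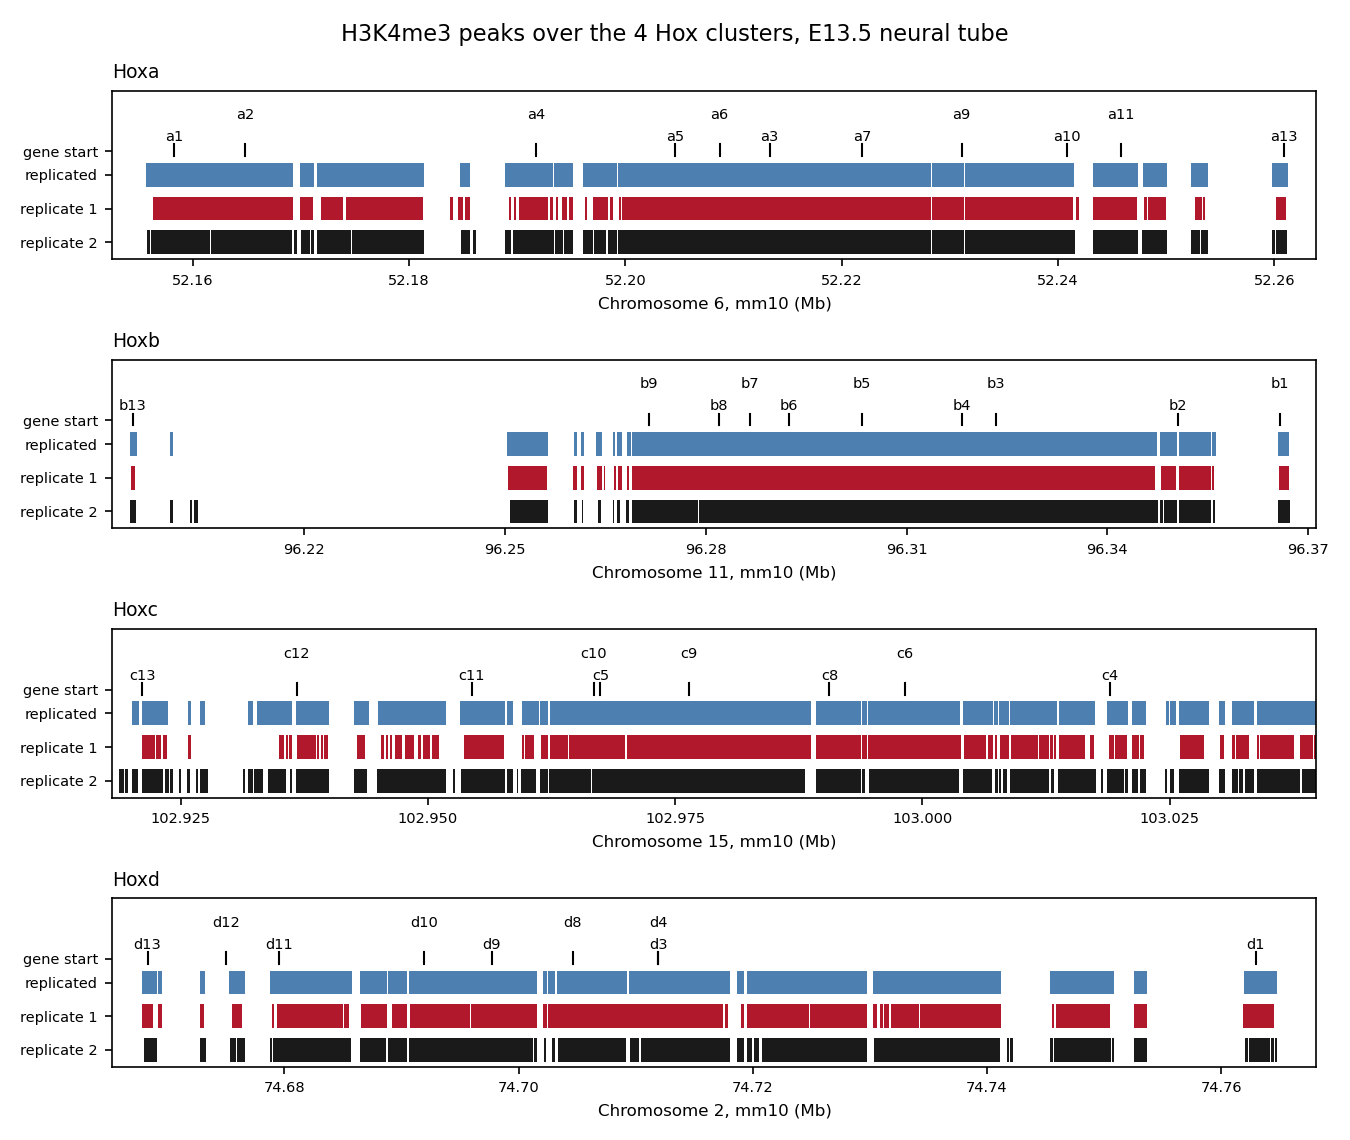
H3K4me3 peaks (filled blocks) over the Hoxa, Hoxb, Hoxc and Hoxd clusters in mm10, with position in Mb on the horizontal axis and the replicated list, replicate 1 and replicate 2 in separate rows and ticks at the start of each annotated Hox gene body. Blocks fill most of the Hoxa (81.8%), Hoxc (81.2%) and Hoxd (73.9%) intervals, and Hoxb (56.7%) has a gap next to Hoxb13.

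The third question was where peaks lay relative to genes. Of the 24509 replicated peaks on assembled chromosomes, 16773 (68.4%) lay within 1 kb of an annotated start site, against 10.6% on average after shifting. In the replicates' own lists the share was 62.2 ± 0.311% (SD, n = 2). Peaks at start sites had a median length of 2055 bp and a median signal value of 43.7. The 942 exonic peaks away from start sites had a median signal value of 5.19, the 3420 intronic peaks 3.89 and the 3374 intergenic peaks 5.72.

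A few peaks far from any start site were as strong as promoter peaks. Of the 2940 replicated peaks over 10 kb from a start site, the strongest (70.7) was 13336 bp long on chromosome 15, 85669241 to 85682576, within an intron of the long noncoding RNA gene Lncppara. The next (67.1) was intergenic on chromosome 9, 32031318 to 32034364, 81.8 kb from the nearest protein-coding start site, that of Arhgap32. The others were an intergenic peak 11.3 kb from Gpr161 (65.2, chromosome 1, 165280667 to 165284470), an intronic peak in Ldb3 (59.2, chromosome 14, 34548031 to 34549882) and an intergenic peak 32.3 kb from Pum2 (58.8, chromosome 12, 8640098 to 8641811). Each of the 5 overlapped a peak in both replicates.

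The last question was how far the replicates shared peaks. Of the peaks of replicate 1, 85.4% overlapped a peak of replicate 2 by at least 1 bp, and 86.0% of those of replicate 2 did so in return (mean 85.7 ± 0.395%, SD over these 2 directions). Both directions describe the same pair of replicates, so this SD does not measure a spread between replicates. After shifting, the share was 2.90% on average for each. Peaks without a partner were short and weak. In replicate 1 their median length was 243 bp and their median signal value 2.99, against 1343 bp and 21.8 for shared peaks. In replicate 2 the values were 226 bp and 3.004 against 1250 bp and 19.1. Across 23617 paired peaks, which are not independent replicates, the signal values had a Spearman correlation of 0.948 and a Pearson correlation of 0.974 on the log2 scale.

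The replicated list was a subset of the pooled list. It held 24521 of the 30902 pooled peaks (79.4%, 95% Wilson interval 78.9 to 79.8%, which covers counting error only), each with the same start and end. It held 8.70% of the weakest decile of pooled peaks by signal value, 24.0% of the next and 64.1% of the third, and 100% from the fifth upward. Pooled peaks that were left out had a median length of 238 bp, against 1495 bp for those kept. None of the 6381 peaks left out overlapped peaks of both replicates by at least 0.5 of either peak's length, while 22910 of those kept (93.4%) did. The replicated list was derived from the pooled list and the replicates' lists, so these counts describe how it was made.

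**Figure D4:**
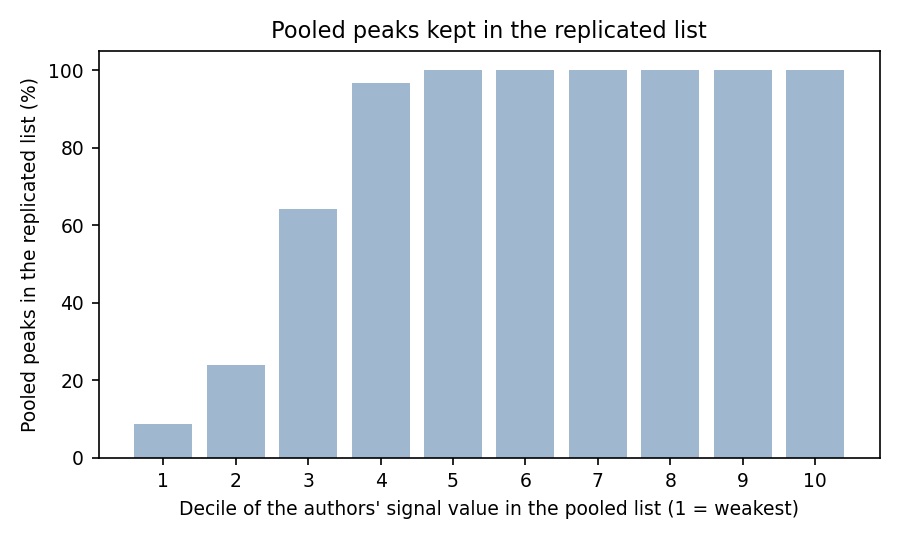
Share of pooled peaks that are in the replicated list (vertical axis, %) by decile of the authors' signal value in the pooled list (horizontal axis, 1 is the weakest). Bars are shares of about 3090 peaks each, rising from 8.70% in the weakest decile to 100% in deciles 5 to 10.

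Few genes were marked in the list of a single replicate. A total of 14548 protein-coding genes were marked in both replicates, 100 in replicate 1 alone and 79 in replicate 2 alone. The strongest of the former were Igflr1 (53.3), whose peaks also lay at Psenen, U2af1l4 and Gm49396, B3gnt4 (39.0), Plin1 (26.9), Zscan10 (14.3) and Rgn (11.7). The strongest of the latter were Gm28035 (36.5), which shares a peak with Lrrc8a, Tchh (34.8), Gm45808 (16.7), Dennd1c (6.99) and Gm3448 (5.36). For the first 4 of the latter and all 5 of the former, a peak of the other replicate lay within 2.5 kb of a start site. Over all such genes this held for 20 of the 100 of replicate 1 and 21 of the 79 of replicate 2 (26.6%). Among the fixed lists, microglia and macrophage genes were over-represented in replicate 2 (Spi1 and Cd68, 2 of the 4 members marked in either replicate, Fisher's exact test, adjusted p = 0.00372). Their signal values there were 3.496 and 3.03, and C1qa of the same list was marked in replicate 1 alone (2.56). No list passed in replicate 1, where the smallest adjusted p of Fisher's exact test was 0.184.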

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

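The test of weak peaks was chosen after the result was seen, and the test of gene lists was set before. Peaks lay in sequence that the comparisons did not use: 12 replicated peaks were on 6 unplaced or unlocalized scaffolds, and no expected number for such sequence was computed, so the count is given as a value only. Their median length was 767.5 bp and their median signal value 12.4, and the lists of the replicates held 13 and 14 such peaks.

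The genes marked in the list of 1 replicate alone, 179 in all, were weighed as a pattern of their own. Their strongest peak was below the lower quartile of start-site peaks of that replicate for 173 of them (96.6%), which is consistent with weak peaks near the calling threshold. A difference in dissected cell types between the replicates also stays open, because 1 fixed list, microglia and macrophage, was over-represented among the genes of replicate 2. That call rests on Spi1 and Cd68, both weak, and C1qa of the same list was marked in replicate 1 alone. The largest expected count behind these tests was 0.265 genes, so a smaller difference would not have been seen.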

How the results depend on the processing

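Alternatives other than basic transcripts, leaving out genes that share every peak, counting each domain once, matching on signal value and the count of list calls were set before the data were examined. Of all results and settings, 319 kept their direction and side of the threshold, or moved by less than the spread between replicates or the interval, except that 3 list shares and 7 list breadths that passed in neither setting had the other sign. The cause of the changes below was not tested unless stated. Depth is unknown and limits what an absent peak shows.

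The mean share of peaks found in the other replicate was 80.6% with at least 0.5 of the peak's length, 73.9% with reciprocal 0.5, 88.1% with a q of 0.01 or lower and 95.8% for the strongest 20000 peaks, and fewer weak peaks enter the last 2. The Spearman correlation was 0.979 with −log10 p and 0.943 for pairs overlapping reciprocally by 0.5. With a q of 0.01 or lower, 83.5% of pooled peaks were replicated. The share of peaks at a start site was 65.8% with 0.5 kb, 76.4% with 2.5 kb, 59.7% in the pooled list and 61.9 to 62.4% with either replicate left out. The share of genes marked was 66.2%, 67.6%, 67.1% and 66.7 to 66.8% in the same order, and 65.6% with basic transcripts. Leaving out either replicate gave 76.1 to 80.8% coverage of Hoxa, 55.1 to 55.9% of Hoxb, 67.9 to 79.1% of Hoxc and 69.5 to 71.3% of Hoxd.

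Matching on CpG observed/expected left 3 of 18 list calls for marking. For 8 of them no count could have passed as higher even before adjustment, since matched genes are nearly all marked (smallest possible p from 0.093 to 1), so the loss cannot show whether they exceed matched genes: progenitor (100%, adjusted permutation p = 0.398), dorsal (100%, 0.962), ventral (100%, 0.949), Hox (100%, 0.198), cell cycle and housekeeping (100%, 1 each), spinal neuron (96.2%, 1) and forebrain and midbrain genes (90.5%, 0.398), the last below the matched 96.7%. For these 8 lists matched genes were marked at 92.9 to 98.5%, against 66.6% of all protein-coding genes. Most or all of their excess in the exact test therefore went with CpG content. The calls of pan-neuronal (100%, adjusted permutation p = 0.0968), synaptic (100%, 0.13), skeletal muscle (26.7%, 0.398), cardiac (30.8%, 0.0968), microglia (6.67%, 0.173) and liver genes (5.88%, 0.159) also ended, the first 2 at the highest share possible, and erythroid genes (27.8%, 0.918) lay above the matched 22.5%. Pan-neuronal and synaptic genes could not have been marked more often, so the loss of their calls cannot show this either. Their matched genes were marked at 86.6 and 87.5%. Cardiac genes did not pass with 2.5 kb (46.2%, 0.156) or the pooled list (46.2%, 0.16), nor endothelial genes with 2.5 kb (93.3%, 0.0628). Mesenchyme genes passed without genes that share every peak (88.9%, 0.0203).

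For breadth, with no joining dorsal (2437 bp, adjusted permutation p = 0.852) and ventral genes (2605.5 bp, 0.617) did not pass and synaptic genes did (3074 bp, 0.0374). With 3 kb joining, forebrain (2141 bp, 0.257) and housekeeping genes (3526.5 bp, 0.0512) did not pass. Against CpG-matched lists synaptic (3074 bp, 0.0224) and mesenchyme genes (3307 bp, 0.0227) passed. Against signal-matched lists synaptic (3074 bp, 0.00996), glial (2570.5 bp, 0.0404) and mesenchyme genes (3307 bp, 4.57e-05) passed and housekeeping genes did not (3457.5 bp, 0.0813). There the medians of forebrain (1546 bp, 0.0759) and endothelial genes (2365.5 bp, 0.0166) lay above those of the matched lists, 1056 and 1331 bp. Mesenchyme genes also passed with the pooled list (3591 bp, 0.0434), with each domain counted once (3307 bp, 0.0475) and without replicate 1 (0.0495), at 3085 to 3266 bp with either replicate left out.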

Other observations

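The tests of cells of other types, of joining in the dorsal and ventral lists alone and between the spinal and forebrain lists, of CpG content in the mesenchyme and neural crest lists alone, of CpG content and signal value in parts of the neural lists, of germline genes in the pooled list, of Hox groups and of spinal against forebrain factors, and the matching on signal value, were chosen only after the results were seen. MicroRNA genes of the nervous system lay in some of the broadest domains without a protein-coding start site, and these loci were picked after their values were seen. Other domains of this kind were broad as well, such as those on chromosome 15 from 85669241 (14.2 kb), at Mir125b-1 (11.7 kb) and at Malat1 (9.89 kb), likewise named after their values were seen. All 3 loci of Mir9, a microRNA of neural progenitors, were covered: 29.8 kb at Mir9-2 on chromosome 13 (29.5 ± 0.0184 kb in the replicates, SD, n = 2), 23.4 kb at Mir9-1 on chromosome 3 (22.6 ± 0.827 kb) and 17.0 kb at Mir9-3 on chromosome 7 (19.4 ± 4.12 kb). The loci of the neuronal microRNA Mir124a had 15.9 kb at Mir124a-2 (15.9 ± 0.0658 kb), 9.85 kb at Mir124a-1 (9.44 ± 0.0134 kb) and 7.16 kb at Mir124a-3 (7.08 ± 0.0693 kb). These 6 loci were between the percentiles 98.5 and 99.98 of all 21025 domains by length.

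Spinal and forebrain transcription factors differed in breadth when set directly against each other. The median was 6887 bp over 25 spinal neuron factors and 1546 bp over 19 forebrain and midbrain factors (two-sided permutation test of list labels, p = 0.00033). Within the range of CpG observed/expected that both lists share, the medians were 7201 bp over 22 genes and 1546 bp over 19 genes (permutation p = 0.00022). That range left out no forebrain or midbrain gene and few spinal genes, so it could hardly change the result. The median ratios of the full lists were already close, at 0.774 for spinal and 0.761 for forebrain and midbrain factors. With peaks left unjoined the medians were 3311 and 1542 bp (permutation p = 0.0045), so the gap was smaller but not gone. The median signal values of the 2 lists were 16.1 and 11.4 (permutation p = 0.0568), and the forebrain median of 1546 bp was above the 1056 bp of lists matched on signal value. Of 11528 genes with CpG-rich start sites 144 were unmarked, and among the 7 CpG-rich genes of the pluripotency and germline list 4 were, the meiotic and germline genes Ddx4, Mael and Sycp3 and the signalling cofactor gene Tdgf1 (Fisher's exact test, p = 7.94e-07, against 1.22% of other CpG-rich genes). Tdgf1 had a weak peak in replicate 2 alone (2.66), and in the pooled list it was marked and 3 of the 7 were not (Ddx4, Mael and Sycp3, named after their values were seen, Fisher's exact test, p = 4.86e-05). The test with the replicated list was set before its result was seen, left out once the result was known and then put back. The lower signal values of Hox groups 10 to 13 than of groups 1 to 9 were tested after they were seen (permutation p = 2e-05, the smallest possible).

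Breadth was not confined to the lists weighed here: neural crest (adjusted permutation p = 6.4e-05) and housekeeping genes (0.0189) also passed as broader. Forebrain and midbrain factors were narrower (0.00256). Broad domains were found at 6 neural lists, taken because they had passed that test: progenitor, dorsal, ventral, spinal neuron, pan-neuronal and Hox. Without joining of neighbouring peaks 4 of them were still broader than random lists, with medians of 4909 bp for progenitor, 5128 bp for pan-neuronal, 3311 bp for spinal neuron (from 6887 bp) and 10909 bp for Hox genes (from 62443 bp), so joining adds to the breadth without accounting for these calls, and it may account for the dorsal and ventral lists, where the smaller adjusted p without joining was 0.617 (2437 and 2605.5 bp, from 3735 and 3565 bp). All 6 were still broader than lists matched on start-site CpG content, which argues against CpG content as the whole cause: the matched reference was broader than the unmatched one for 2 lists, progenitor and spinal neuron (2530.5 and 2557 bp), and narrower for the others, although 0 of the 6 had a median CpG ratio below random lists. The 6 lists had been chosen as broader, so passing again was likely where matching narrowed the reference. There the comparison rests on the matched medians themselves, 2213.5 to 2427 bp. All 6 were also broader than lists matched on signal value, which argues against stronger peaks being called wider as the whole cause of their breadth: 3 lists (dorsal, ventral and spinal neuron) had median signal values below random lists (adjusted permutation p = 0.000594, 0.000128 and 8e-05), progenitor and pan-neuronal genes had 6465.5 and 5402 bp against the matched 2334.5 and 2439 bp (adjusted p = 4.57e-05 each), and Hox was the 1 list for which matching made the reference broader (2563 bp). For the lists other than Hox, passing again was likely, since matching on signal value narrowed their reference. The Hox result counted 39 genes that share domains as separate. With each domain counted once, 15 Hox domains had a median of 6845 bp, a value set only against lists not matched on signal value. The matched reference was as low as 1356 bp for ventral genes, so breadth did vary with signal value. Of the 16 lists tested, 11 passed this matching as broader, mesenchyme and endothelial genes among them, so passing it was not particular to these 6. No biological explanation was tested, and which neural lists passed varied, since synaptic and glial genes passed against lists matched on signal value (adjusted permutation p = 0.00996 and 0.0404) and not against all marked genes (0.0952 and 0.812).

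Genes listed for cell types outside the neural tube carried peaks: 43 of the 48 genes of the mesenchyme, endothelial and neural crest lists (89.6%), of which Isl1 and Pou4f1 are also in the spinal neuron list. Whether cells of the neural tube itself use other members of these lists, the neural crest list above all, was not examined. Lists matched on CpG observed/expected had 68.6% marked (permutation p = 0.0002, the smallest that 10000 matched lists can give), and without the endothelial list 29 of 33 were marked (87.9% against 74.3%, permutation p = 0.0074), though alone mesenchyme (88.9% against 72.9%, adjusted p = 0.159) and neural crest genes (86.7% against 76.1%, 0.328) did not pass and the endothelial list did. This argues against a mark at CpG-rich start sites whatever the lineage as the whole cause, but the CpG-poor members were not marked as often as the CpG-rich ones (9 of 13, 69.2%, exact 95% interval 38.6 to 90.9%, against 26 of 26), which the prediction had also asked for. Cells of other types in the dissected tissue may be a source: of 13 terminal genes of mesenchyme, vessel and blood cells 4 had a replicated peak of their own, Dcn (2.26), Col1a2 (14.5), Pecam1 (4.01) and Cdh5 (3.76), and none of the 7 globin genes did, so that in mesenchyme and vessel cells alone, a set chosen after that result, 4 of 6 had a peak. These signal values are at or under the percentile 8.93 of marked genes, and marking of these genes in neural cells was not tested and stays open. The 6 genes are themselves members of the mesenchyme and endothelial lists. Of all protein-coding genes 66.6% were marked, and 11.3% of those with a CpG ratio under 0.4. The count of 4 of 6 therefore cannot decide whether such cells were present.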
